A study of Gallus gallus with 4 samples.

How the data were processed

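PolyA RNA was sequenced from 4 libraries of electroporated chick retinal explants, 2 of the ThrbCRM1 population and 2 of the UbiqC population, with groups and letters taken from the library titles. Per the submitters' processing notes, transcripts were quantified with kallisto and compared with sleuth against galGal5, with versions not given in the sources used here. The deposited expected counts per transcript and TPM per transcript were made by the authors with kallisto, per the submitters' processing notes, and the transcript lengths and effective lengths (other values, in bases) came in the same deposited tables. The authors' deposited comparison gives p-values and q-values, and effects on a natural log scale, negative where ThrbCRM1 is higher. The authors' deposited transcript table holds a signal that equals kallisto TPM times 1 factor per library, between 0.967 and 1.035. The authors' deposited read-class sheet gives the fraction of reads in each class, made with bowtie per its name, with the classes not defined further in the sources used here.

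Each library listed 57401 transcripts, of which 35667 carried a gene name, giving 18292 genes. The named transcripts held between 99.8015% and 99.8292% of the estimated counts. Of 21 symbols that had turned into dates, 19 were named through the reference gene table (bGalGal1.mat.broiler.GRCg7b), which was used for names only, and no coordinates are given because its assembly differs from galGal5. Expected counts were summed by gene and rounded to whole numbers. EGFP and TdTomato were left out of the gene tables. Estimated counts of genes that share sequence with a close relative are uncertain, since reads could be split between them.

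The main test was edgeR 4.0.16 (R 4.3.3), with TMM factors between 0.988 and 1.007, filterByExpr with a minimum count of 10, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. This left 16771 genes, 2 residual degrees of freedom and a common biological coefficient of variation of 10.6%. Fold changes are ThrbCRM1 minus UbiqC on the log2 scale with their standard errors, and levels are CPM as mean ± SD of 2 libraries. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with prior count 2 and a correlation of 0.01, adjusted over 29 lists, and again with an estimated correlation, under which camera called 0 lists, with an unadjusted p below 0.05 for 1, against 15 with the preset correlation. The directional fry test, which does not compare a list with other genes, called 23. Lists needed 3 tested members. DESeq2 1.42.0 was an alternative. List results given with DESeq2 came from limma cameraPR on its Wald statistics with the preset correlation, so the set test changed as well.

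The lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule took 7 genes in every case (THRB, OTX2, ONECUT1, OLIG2, LHX2 and PAX6 among them), the 8 greatest increases and 8 greatest decreases among symbol-bearing genes past the test with a mean of at least 10 CPM and separated libraries, and the 2 members of each list with the smallest edgeR p. Some genes that the rule takes are not reported here. The 29 lists covered multipotent and restricted progenitors, Notch, photoreceptor, horizontal, ganglion, amacrine, bipolar and glial genes, pigment epithelium and ciliary margin, lens, blood and immune, and endothelial and mesenchymal genes, G1 to S, G2 and M and cell cycle exit genes, neuronal differentiation, FGF, Wnt, BMP, hedgehog and retinoic acid pathways, axis patterning, junctions, adhesion, stress, apoptosis and glycolysis. Listed symbols with no match in the tables, such as CRX, are not analysed here.

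The alternatives were the letter as a block, DESeq2 size factors, the DESeq2 test, no filter on low counts, at least 5 CPM in 2 libraries, transcript length offsets, limma on log2(TPM + 1) with a filter at 1 TPM, on log2(TPM + 0.1), without a filter, and each library left out in turn. The labels do not say that A and B came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The libraries of a group differed by more than counting noise (chi-square per degree of freedom 8.27 in ThrbCRM1 and 9.89 in UbiqC). The edgeR test was checked on simulated data for this comparison with 16431 genes, few of them changed. It recovered 24 of 49 genes changed 1.5-fold, 34 of 50 changed 2-fold, 46 of 50 changed 4-fold and 47 of 49 changed 8-fold. There were 12 unchanged genes among 163 calls. With so few changed genes the adjusted threshold was stricter than in the data, so these shares may understate recovery there. Python steps used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.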

Results

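RNA from sorted chick retinal cells was sequenced to compare cells marked by a reporter of fate-restricted progenitors with the remaining electroporated cells. Retinal explants of embryonic day 5 had received a plasmid in which ThrbCRM1, a regulatory element of the thyroid hormone receptor gene THRB, drove GFP, together with a UbiqC plasmid that drove TdTomato in electroporated cells. After about 20 hours of culture the cells were sorted into a GFP-positive, TdTomato-positive population, called ThrbCRM1 here, and a population positive for TdTomato alone, called UbiqC here. Each population had 2 libraries, A and B. The totals were 30959178 estimated counts in ThrbCRM1 A, 16087500 in ThrbCRM1 B, 15673010 in UbiqC A and 31659766 in UbiqC B, so each group held a deeper and a shallower library. The 10 most abundant genes took between 4.22% and 4.77% of the counts of a library.

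The reporters followed the sort. EGFP stood at 9805 TPM in ThrbCRM1 A and 15147 TPM in ThrbCRM1 B, against 150 TPM in UbiqC A and 156 TPM in UbiqC B. TdTomato, the reporter shared by both gates, stood at 3547 and 14505 TPM in ThrbCRM1 A and B and at 2124 and 5637 TPM in UbiqC A and B. It differed 4.09-fold between the ThrbCRM1 libraries and 2.65-fold between the UbiqC libraries, and the ranges of the groups overlapped.

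The comparison of ThrbCRM1 with UbiqC cells asked how the reporter-marked population differs from the remaining electroporated cells. THRB itself, the gene whose element marked the sort, stood at 892 ± 167 CPM (SD, n = 2) in ThrbCRM1 and at 22.3 ± 2.30 CPM in UbiqC, a log2 fold change of 5.31 ± 0.17 (SE). OTX2, a transcription factor needed for photoreceptors, rose from 59.5 ± 1.56 to 1192 ± 144 CPM (log2 fold change 4.33 ± 0.11), and ONECUT1, a factor of horizontal cell and cone development, rose from 17.7 ± 5.65 to 150 ± 5.91 CPM (3.04 ± 0.19). OLIG2, a bHLH factor of restricted progenitors, rose by 1.15 ± 0.12. LHX2, a homeobox gene of retinal progenitors, fell from 108 ± 0.0843 to 67.6 ± 0.969 CPM (-0.68 ± 0.07). PAX6 stood at 279 ± 45.7 CPM in ThrbCRM1 and 350 ± 8.57 CPM in UbiqC and did not pass the test (edgeR adjusted p = 0.0657, log2 fold change -0.32). The edgeR adjusted p-values of the other 5 genes were at most 0.000662. PAX6 passed with the DESeq2 test, with the letter as a replicate block and without ThrbCRM1 A, where its log2 fold change was -0.50.

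In all, 6839 of 16771 tested genes (40.8%) passed the edgeR quasi-likelihood test, 3333 higher and 3506 lower in ThrbCRM1, and 1452 and 1453 of them differed by at least 2-fold. At least 8-fold differences numbered 293 higher and 160 lower. The unadjusted edgeR p lay below 0.05 for 8264 genes. Both ThrbCRM1 libraries lay on the same side of both UbiqC libraries for 72.0% of tested genes, where chance gives 33.3%. Without ThrbCRM1 A the count of calls was 3846, and without ThrbCRM1 B it was 4546. The authors' deposited table lists 7279 genes with q below 0.05, 3387 higher and 3892 lower in ThrbCRM1. Of 16751 genes in both tables, 6826 passed here and 7237 in the authors' deposited table, 6526 passed in both, and all 6526 had the same direction (odds ratio 282). Both sets of calls came from the same 4 libraries, so their overlap compares methods.

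The genes with the greatest increases included several known from photoreceptors. RBP4B, a retinol-binding protein gene, rose from 44.6 ± 5.54 to 5515 ± 844 CPM (SD, n = 2; log2 fold change 6.94). NR2E3, a photoreceptor nuclear receptor, rose by 6.87, SAMD10 by 6.81, RCVRN, which encodes the calcium sensor recoverin, by 6.44, RBP3, an interphotoreceptor retinoid-binding protein gene, by 6.43, and RP1, an axonemal protein gene of photoreceptors, by 6.38. RXRG, a nuclear receptor of cones, rose from 18.8 ± 0.433 to 1498 ± 206 CPM, and DMBX1, a homeobox gene, rose by 6.09. The greatest decreases fell on VEPH1 (-4.63), CYP1B1, an enzyme that can make retinoic acid (-4.50, from 701 ± 63.9 to 30.8 ± 4.84 CPM), SLC1A3, a glutamate transporter of glia and progenitors (-4.49), S100A11 (-4.20) and AvBD5, a defensin gene (-4.20). CYR61, a matricellular protein gene, fell from 355 ± 11 to 20.9 ± 1.88 CPM (-4.07), and ADAMTS19 (-4.06) and FGFRL1 (-4.04) fell as well.

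**Figure D1:**
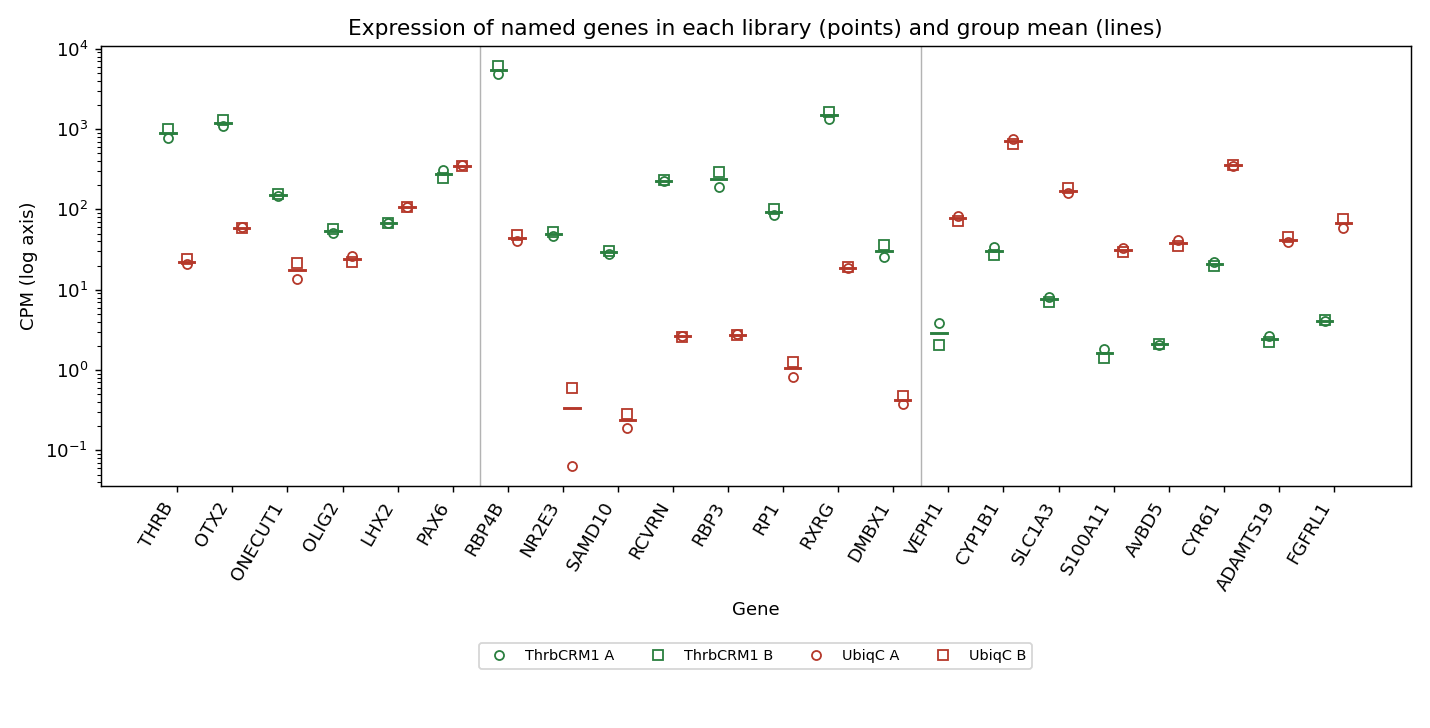
Expression in CPM on a log axis of 6 genes named in every case (left), the 8 with the greatest increases (middle) and the 8 with the greatest decreases (right), in the 4 libraries (circles for A, squares for B) with lines at the mean of each group. Both ThrbCRM1 libraries of THRB lie far above both UbiqC libraries (mean 892 against 22.3 CPM), while PAX6 (279 against 350 CPM) lies close together.

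Among 14 tested genes of the list of cone and horizontal cell restricted progenitors, 10 rose and 4 fell (camera adjusted p = 0.00717, limma; adjusted p = 0.41 with an estimated correlation). NEUROD1, a bHLH factor, rose from 22.9 ± 0.902 to 567 ± 108 CPM (SD, n = 2). DLL4, a Notch ligand, rose from 39.6 ± 5.97 to 319 ± 60.7 CPM and ATOH7 rose by 1.73, while HES6 (-1.35) and DLL1 (-0.62) fell. These 4 genes were named after their values were seen. FOXN4, also named then, fell by 0.41. Its call was lost without ThrbCRM1 B and with limma on log2(TPM + 1) without a filter. Of 13 Notch ligands and proneural factors 7 rose and 4 fell (limma camera adjusted p = 0.179, and 6.6e-05 with DESeq2), among them INSM1, which rose by 2.16, and 8 rose and 5 fell adjusted over the list alone. Of 20 Notch receptors and effectors 3 rose and 14 fell (limma camera adjusted p = 0.000882; adjusted p = 0.41 with an estimated correlation). ID3, an inhibitor of bHLH factors, fell from 157 ± 10.5 to 12.1 ± 0.497 CPM, and DTX4 fell by 2.99. Of 21 multipotent progenitor genes 6 rose and 12 fell, and 6 rose and 14 fell adjusted over the list alone (limma camera adjusted p = 0.0439; adjusted p = 0.41 with an estimated correlation). FZD5, a Wnt receptor gene, fell from 353 ± 7.58 to 52.8 ± 3.48 CPM, and SFRP1 (-2.66) and NR2E1 (-3.97), the latter named after its value was seen, fell as well. Among the 6 that rose, FGF19, a fibroblast growth factor gene, stood at 797 ± 85.7 against 45.7 ± 8.67 CPM. Several genes stood in more than a single list, so the list results are not separate. ID1, ID2, ID3 and ID4, which all fell, were in both the Notch receptor and BMP lists. FZD5 and SFRP1 were in the multipotent and Wnt lists. NEUROD1, DLL4, ATOH7, INSM1, HES6 and DLL1 were among the genes in both the restricted progenitor and Notch ligand lists. The call of the multipotent list was lost without UbiqC B (limma camera adjusted p = 0.0722) and with the filter at 5 CPM (0.0661).

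Genes of differentiated retinal neurons rose in part. The sort went by the reporters alone, so these levels do not tell progenitors from differentiating cells within ThrbCRM1. Of 27 photoreceptor genes 17 rose and 2 fell, and 17 rose and 3 fell adjusted over the list alone (limma camera adjusted p = 4.8e-06; adjusted p = 0.41 with an estimated correlation). The 2 that fell, GNAT2 (-0.59) and IMPG1 (-0.78), named after their values were seen, encode a cone transducin subunit and a matrix proteoglycan. Of 11 horizontal cell genes 7 rose and 3 fell (limma camera adjusted p = 0.0439; adjusted p = 0.62 with an estimated correlation). PTF1A, a factor of horizontal and amacrine cells, rose from 2.39 ± 0.137 to 82.5 ± 11.5 CPM (SD, n = 2) and LHX1 rose from 7.24 ± 1.14 to 87.9 ± 16.7 CPM. The 3 that fell, named after their values were seen, were PROX1 (-2.84), ISL1 (-1.84) and LNX1 (-1.24). The horizontal list lost its call without ThrbCRM1 A and with the letter as a replicate block (limma camera adjusted p = 0.0682). At the 5 CPM filter its limma camera adjusted p was 0.264, and on the TPM scales it lay between 0.0611 and 0.129. Of 15 amacrine cell genes 9 rose and 2 fell (limma camera adjusted p = 0.00717; adjusted p = 0.43 with an estimated correlation), BARHL2 by 4.06 among them, and the call was lost at the 5 CPM filter (0.104). PTF1A, TFAP2A, TFAP2B and PROX1 stood in both lists. Of 31 ganglion cell genes 9 rose, STMN2 by 1.75 and L1CAM from 22.6 ± 1.30 to 63.8 ± 0.961 CPM among them, and 8 fell (limma camera adjusted p = 0.958). RBPMS (-1.19), RBPMS2 (-1.49) and EBF3 (-1.51), named after their values were seen, were among the 8 that fell. POU4F1, POU4F2 and POU4F3, also named then, did not pass the test. STMN2 stood in the neuronal differentiation list as well. The ganglion list had a median of -0.25 and an upward direction by fry that was not called (limma fry adjusted p = 0.263). Of 9 bipolar cell genes 3 rose and 3 fell, PRKCA (-2.18) and VSX1 (-1.17), and 3 rose and 5 fell adjusted over the list alone (limma camera adjusted p = 0.335). Of 29 neuronal differentiation genes 17 rose and 3 fell, SYT4 rising by 2.47 and MAP2 by 1.80 (limma camera adjusted p = 0.000882; adjusted p = 0.41 with an estimated correlation), and 17 rose and 4 fell adjusted over the list alone.

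Lists named for other cell types were mixed, and a fall in them does not show that such cells were fewer. The glial list held SLC1A3, a gene of glia and progenitors, so its fall does not tell glia from progenitors. Of 12 glial genes 0 rose and 9 fell (limma camera adjusted p = 1.8e-05; adjusted p = 0.41 with an estimated correlation), CA2, a carbonic anhydrase gene, from 4116 ± 224 to 348 ± 18.4 CPM (SD, n = 2) and FABP7 from 5178 ± 161 to 641 ± 39.5 CPM. Of 18 genes of the pigment epithelium and ciliary margin 4 rose and 6 fell, GJA1 (-3.75) and RLBP1 (-2.12) (limma camera adjusted p = 0.861), with a median of 0.13 and a mean of -0.12. Of 10 lens genes 2 rose and 5 fell, CRYAB (-3.55) and ASL2 (-3.43) (limma camera adjusted p = 0.218). Of 3 blood and immune genes 1 rose, PTPRC by 1.04, and 1 fell, TAL1 (-3.10) (limma camera adjusted p = 0.861, list median 0.74, mean -0.44, downward by fry but not called, limma fry adjusted p = 0.797), and both calls were lost without ThrbCRM1 A. TAL1 stood at only 0.811 ± 0.203 CPM in UbiqC and 0.0964 ± 0.0448 CPM in ThrbCRM1, so the size of its fall is uncertain. Of 17 endothelial and mesenchymal genes 3 rose, COL6A2 by 2.69 among them, and 9 fell, COL5A1 (-3.72) among them (limma camera adjusted p = 0.0607, and 0.00449 with DESeq2).

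Of 38 G1 to S phase genes 1 rose, 20 fell and 17 did not pass the test, and 1 rose and 23 fell adjusted over the list alone (limma camera adjusted p = 0.000254; adjusted p = 0.53 with an estimated correlation). E2F1, an S phase transcription factor gene, fell from 503 ± 54.8 to 240 ± 0.363 CPM (SD, n = 2). Of 42 G2 and M phase genes 4 rose, 11 fell, ANLN (-0.61) and CDK1 (-0.42) among them, and 27 did not pass, and 3 rose and 11 fell adjusted over the list alone (limma camera adjusted p = 0.378). CDK1 lost its call without ThrbCRM1 A. MKI67, a proliferation marker named after its value was seen, stood at 730 ± 76.6 CPM in ThrbCRM1 and 702 ± 57.4 CPM in UbiqC (edgeR adjusted p = 0.690). Of 15 cell cycle exit genes 10 rose, BTG2 by 1.58 and GADD45A by 1.37, and 3 fell, and 10 rose and 4 fell adjusted over the list alone (limma camera adjusted p = 0.0337; adjusted p = 0.41 with an estimated correlation). That call was lost without ThrbCRM1 A, without UbiqC B and with the letter as a replicate block (limma camera adjusted p = 0.0721). The authors' cell cycle list was deposited with these samples, how its genes were chosen is not given in the sources used here, and it is not taken as independent evidence of direction. It had 109 tested genes, of which 13 rose and 38 fell, and 14 rose and 41 fell adjusted over the list alone (limma camera p = 0.0197; p = 0.133 with an estimated correlation). In the authors' deposited table, q-values of 59 of 111 genes were below 0.05, 46 higher in UbiqC and 13 higher in ThrbCRM1.

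Signaling genes fell in ThrbCRM1 in several pathways. Of 12 hedgehog genes 2 rose and 10 fell, GLI1, a pathway target, from 73.4 ± 6.45 to 10.0 ± 0.391 CPM (SD, n = 2) and SMO (-2.10). Of 15 retinoic acid genes 1 rose and 10 fell, CRABP2 (-2.76) among them. Of 18 BMP genes 2 rose and 11 fell, ID1 (-3.36) among them, and 2 rose and 12 fell adjusted over the list alone. The limma camera adjusted p of each of these 3 lists was 0.000882 (adjusted p = 0.41 with an estimated correlation). Of 22 Wnt genes 3 rose and 13 fell (limma camera adjusted p = 0.00509; adjusted p = 0.41 with an estimated correlation). Of 18 FGF and MAPK genes 4 rose and 10 fell (limma camera adjusted p = 0.148), with a median of -0.62 and an upward direction by fry that was not called (limma fry adjusted p = 0.263). FGF3 rose from 1.22 ± 0.159 to 34.3 ± 1.34 CPM. SHH, named after its value was seen, rose by 2.39.

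Of 18 retinal axis patterning genes 3 rose and 9 fell, EFNB1 (-2.10) and EPHB2 (-2.06), and 3 rose and 11 fell adjusted over the list alone (limma camera adjusted p = 0.0337; adjusted p = 0.41 with an estimated correlation). The call was lost without ThrbCRM1 A, without UbiqC B and with the letter as a replicate block (limma camera adjusted p = 0.0676). Of 27 apical junction and polarity genes 7 rose and 11 fell, CRB2 (-2.15) and SHROOM3 (-2.05), and 8 rose and 11 fell adjusted over the list alone (limma camera adjusted p = 0.591, and 0.0343 with DESeq2, median 0.04, mean -0.27). Of 34 adhesion and migration genes 13 rose, ROBO2 by 1.54 among them, and 15 fell, DAB1 (-1.49) among them, and 14 rose and 16 fell adjusted over the list alone (limma camera adjusted p = 0.861, median -0.10, mean 0.05). Of 23 immediate early and stress genes 6 rose and 7 fell, with CHAC1 up by 1.35 and EGR1 down (-1.71) (limma camera adjusted p = 0.921). Of 19 apoptosis and p53 genes 8 rose, BCL2L1 by 1.22 among them, and 6 fell, BAK1 (-1.66) among them (limma camera adjusted p = 0.861, median 0.11, mean -0.19). Of 27 glycolysis and hypoxia genes 2 rose and 11 fell, SLC2A1, a glucose transporter, from 1093 ± 8.55 to 231 ± 19.0 CPM (SD, n = 2) and LDHB (-1.61), and 3 rose and 13 fell adjusted over the list alone (limma camera adjusted p = 0.0653). That list passed with DESeq2 (0.00272) and without ThrbCRM1 B (0.0430). In the lists for which no separate count is given, the counts adjusted over the list alone equalled those over all genes.

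**Figure D2:**
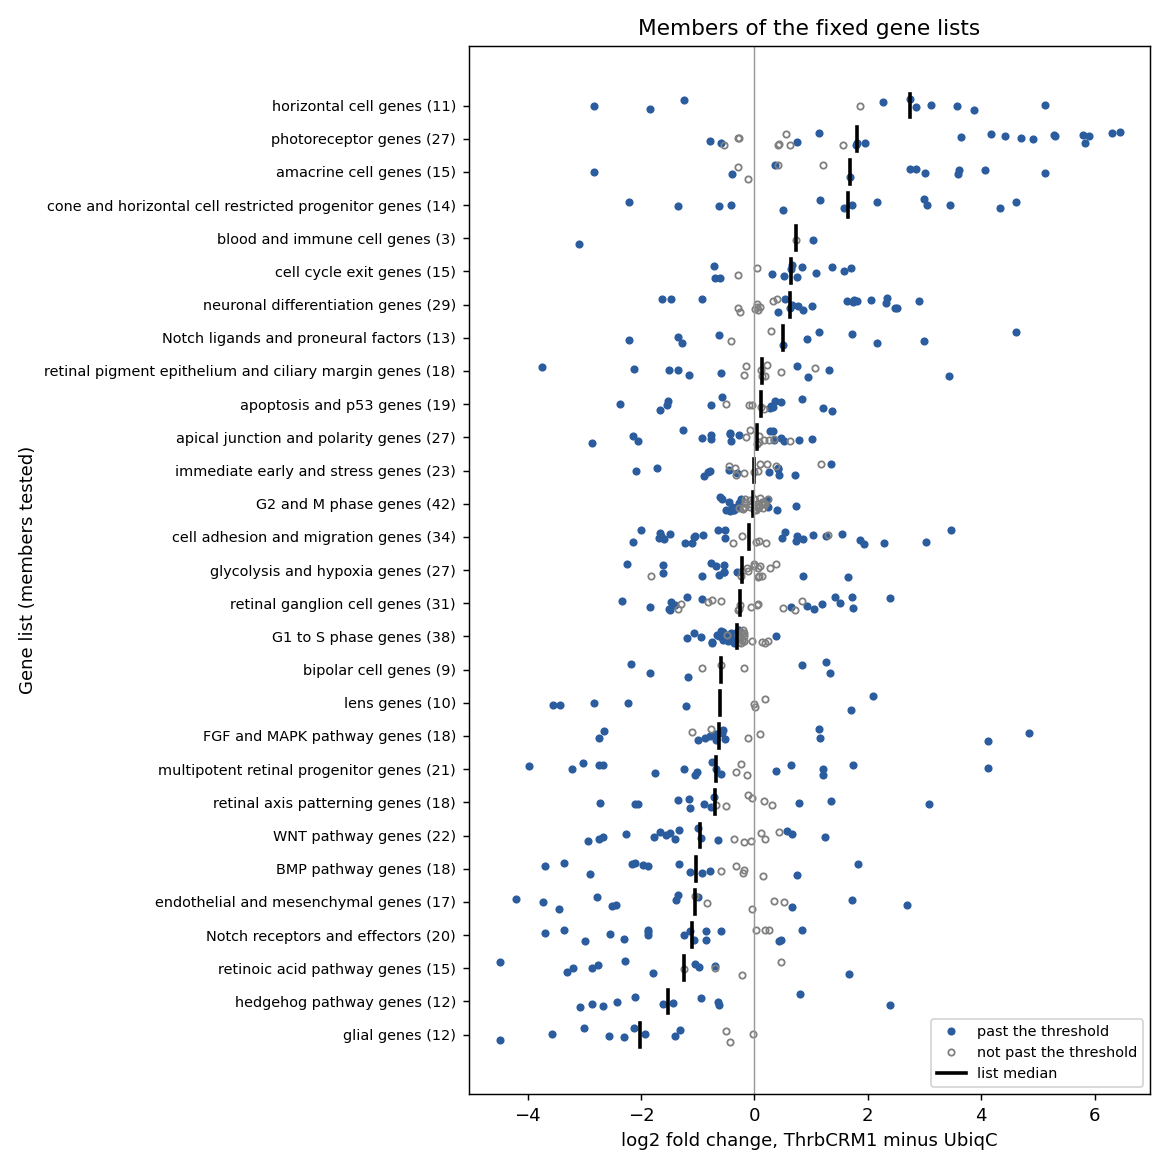
Log2 fold changes (ThrbCRM1 minus UbiqC) of the members of the 29 fixed lists, with the number tested in brackets. Filled points passed the test, open points did not, and the bar is the list median. The photoreceptor list has members up to 6.44 and the glial list has its median at -2.02.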

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

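The tests weighed in this part were chosen only after the results they bear on were seen. EGFP averaged 12480 TPM in the ThrbCRM1 libraries and lay between 150 and 156 TPM in the UbiqC libraries, a signal outside the gene comparison. The read class ThrbCRM1-GFP of the authors' deposited table averaged 1.695% of reads in ThrbCRM1 and lay at 0.02% and 0.03% in UbiqC. Reads the authors left unaccounted averaged 2.64% in ThrbCRM1 (2.38% to 2.90%) and lay between 1.28% and 1.69% in UbiqC. Transcripts with no gene name averaged 0.197% of estimated counts in ThrbCRM1, with UbiqC between 0.171% and 0.190%. These differences were not tested.

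Genes that rose in ThrbCRM1 were also read in UbiqC, and EGFP-positive cells or RNA carried into UbiqC may account for part of that. EGFP in UbiqC stood at 1.66% of its ThrbCRM1 share for letter A and 1.07% for letter B, and the higher value times the ratio of both, 2.56%, was taken as the bound. The 10 risen genes of restricted progenitors had a median of 17.42% (quartiles 9.55% and 32.7%), with 0 at or below 1.66%, which argues against carry-over in proportion to EGFP. For the 12 risen photoreceptor genes of at least 10 CPM the median was 2.401% (quartiles 1.73% and 4.05%), and 7 of the 12 lay at or below 2.56% while 5 lay above it, up to SAMD11 at 28.9% and NEUROD4 at 45.4%, so for the list as a set carry-over cannot be told apart from expression in UbiqC cells because its genes lie on both sides of the bound. The ratio was added to the bound, for the spread of the EGFP share, after the photoreceptor values were seen. Without it their lower quartile lay above 1.66%, with 2 of the 12 at or below that value. By that narrower bound the photoreceptor list would have been read against carry-over in proportion to EGFP. Its reading thus depends on the ratio. Carry-over of cells with weak EGFP and early expression in UbiqC cells stay open, untested.

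Progenitor genes were also read in ThrbCRM1, and UbiqC cells carried into those libraries are a candidate explanation. Carry-over alone would leave every such gene at 1 common share of its UbiqC level. The 12 fallen genes of the multipotent list kept between 6.20% (NR2E1) and 66.0% (HES5), and the SD of their log2 fold changes was 1.171, against a standard error of at most 0.214 for a single gene. This argues against carry-over in proportion to the UbiqC libraries as the whole source for the list. The 8 genes with the greatest decreases, picked as such, kept between 3.77% and 6.14% of their UbiqC level. Carry-over at 1 common share could not exceed what these genes kept, while the 12 kept a median of 36.5%. These values argue against such carry-over as more than a small part of the source at the median of the list. Carry-over of a small part of the reads, or of a subset of UbiqC cells, and persisting expression in the ThrbCRM1 cells stay open, untested.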

How the results depend on the processing

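Every gene that passed both under an alternative and in the comparison of all 4 libraries kept its sign. Genes that pass in both of such fits, made on shared libraries, can hardly change sign, so this is a weak check. Of the 5899 DESeq2 calls 5795 were shared. Each left-out library lowered the count of calls, which ranged from 3846 to 6189, with 1888 to 3137 higher and 1958 to 3052 lower in ThrbCRM1. Without ThrbCRM1 A the counts were 3846, 1888 and 1958, and without ThrbCRM1 B 4546 in all with 2323 lower, fits with fewer samples in which the lone library was assumed to vary like the other group. The letter as a replicate block gave 8376 calls and 12 lists, with PAX6 passing (edgeR adjusted p = 0.00811). The horizontal (limma camera adjusted p = 0.0682), cell cycle exit (0.0721) and axis patterning (0.0676) lists were not called with the block. Deviations of libraries that shared a letter correlated at 0.167 over all tested genes and 0.421 over genes of at least 10 CPM. The second principal component of log2 CPM (12.3% of the variance) split the letters in both groups. It stood at 25.7 in ThrbCRM1 A and 26.3 in UbiqC A, against -22.1 in ThrbCRM1 B and -29.9 in UbiqC B. Libraries that shared a letter thus shared a difference, seen in 2 pairs only. The labels do not say what a letter marks, so the main test had no block. Camera called 15 lists, 0 with an estimated correlation and 23 by fry, which asks another question. Other settings gave between 5899 and 6807 calls. Of 1167 values of the 90 named genes under the 13 alternatives, 3 of which lacked a named gene, 1157 kept their direction and side of the threshold, 3 newly passed, 5 lost the call and 2 reversed: MKI67, not past the threshold, was at -0.0539 without ThrbCRM1 B and -0.0302 without UbiqC A (range -0.0539 to 0.1679 over left-out libraries), and the cause was not tested. Of the list results 354 kept their side of the threshold, 15 lost it and 5 gained one, 4 of them with DESeq2 (Notch ligands, endothelial, junction and glycolysis). With DESeq2 the set test changed along with the count model, so these gains cannot be credited to either alone. At these depths and 2 libraries per group, simulated 1.5-fold changes were recovered in 24 of 49 genes. That simulation changed few genes and gave 163 calls, against 6839 in the data. Its adjusted threshold was therefore stricter, and recovery in the data may be higher. What depth alone limits was not tested.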

Other observations

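The gene groups and the contrast of lists in this part were chosen only after the results were seen. Among 8 tested genes of thyroid hormone handling 1 rose and 3 fell. DIO2, the enzyme that activates thyroid hormone, rose from 2.53 ± 0.605 to 101 ± 28.1 CPM (SD, n = 2), while DIO3, which inactivates it, stood at 94.4 ± 2.39 CPM in ThrbCRM1 and 101 ± 0.855 CPM in UbiqC (edgeR adjusted p = 0.270). SLCO1C1, a thyroid hormone transporter, fell from 9.91 ± 0.211 to 0.516 ± 0.277 CPM, and CRYM, a hormone-binding protein gene, fell as well (-1.59). THRA stood at 9.04 ± 0.384 and 10.2 ± 0.504 CPM (edgeR adjusted p = 0.404).

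Of 13 tested genes of the YAP and TEAD pathway, which responds to cell density and tension, 2 rose and 9 fell. The 9 included CYR61, already named among the greatest decreases, and the count does not measure activity of the pathway. YAP1 fell from 72.1 ± 17.8 to 11.3 ± 0.0136 CPM (SD, n = 2), CTGF, a target gene, from 80.4 ± 9.22 to 5.87 ± 0.611 CPM, and WWTR1 from 25.7 ± 0.427 to 9.18 ± 1.05 CPM, whereas TEAD1 rose from 210 ± 15.2 to 396 ± 30.5 CPM. Of 8 further photoreceptor genes 5 rose and 1 fell. OTX5, a homeobox gene of photoreceptors, rose by 5.45, PDE6B by 5.44 and FSCN2 by 5.54, whereas RDH12, a retinol dehydrogenase gene, fell by 0.52.

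The G1 to S list lay lower in ThrbCRM1 than the G2 and M list did, with medians 0.28 apart on the log2 scale. The mean log2 CPM of the G1 to S list minus that of the G2 and M list was -0.96 in ThrbCRM1 A, -0.84 in ThrbCRM1 B, -0.62 in UbiqC A and -0.59 in UbiqC B. A bootstrap over the list members gave 95% bounds of 0.10 and 0.48 for the difference of the medians. It resampled genes as if they were independent and does not measure the spread between libraries. An explanation of the difference was not tested.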
